A study of Rattus norvegicus with 4 samples.

How the data were processed

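Small RNA recovered by RNA immunoprecipitation (RIP) was sequenced from the CA1 region of the hippocampus of adult Wistar rats aged 7 to 8 weeks. The 4 libraries were a Sham library, a library named tGCI26h (transient global cerebral ischemia, 26 h), a library named HPC0h (0 h, an abbreviation the labels do not spell out) and an IgG control library. The series is about piRNAs, small RNAs that bind PIWI proteins, bound to Piwil2. Its design text gives 3 replicates for each group, whereas 1 library per group was analysed here, and the sources used here do not say whether animals were pooled. Per the labels' protocols, adaptors were ligated to the RNA, cDNA was amplified by PCR, amplicons holding inserts near the size of piRNAs were selected, and the libraries were sequenced on an Illumina HiSeq. The submitters' processing notes name cutadapt 1.9.3 and Novoalign 3.02.12 with no role. The genome build and the piRNA database were not given in the sources used here.

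Per the file headers, the deposited raw table holds tag counts per sequence, and this is the unit all comparisons used. It lists 3129 sequences of 21 to 39 nt, of which 126 carry rno_piR names and the other 3003 carry names in the style of novel_88_x12235. A cell is blank where no value is given, and the lowest value in each library is 2, so a blank was taken as 0 counts in ratios and is described as not listed. A blank does not mean that no read was seen: 807 blank cells in Sham, 706 in tGCI26h, 195 in HPC0h and 374 in IgG hold a value in the authors' normalized table. The second deposited table holds, per the file headers, normalized tag counts. Its values were treated as a score, since the authors' values are whole numbers although normalized, and the scaling is not given in the sources used here. It lists 3891 sequences, 762 of them absent from the raw table, and it was not a plain rescaling of the raw table: between 4.23% and 9.55% of its cells lay within 1 of the rescaled raw count. For this work 40 lines of the raw table and 46 of the normalized table had been emptied. No column of values was left unused.

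Columns were matched to libraries by name. The IgG column carries the library's own name, but the other column names (P0, R26 and S) match the titles of HPC0h, tGCI26h and Sham only in part, through the time or the first letter. The names of the 3 Piwil2 libraries rest on that match. Which animals the IgG library came from was not given in the sources used here.

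The raw tables sum to 159215 tags in Sham, 222511 in tGCI26h, 830634 in HPC0h and 668857 in IgG, with 1749, 2102, 2849 and 2646 sequences listed. These are the tags of the listed sequences, which stand in for library totals because the number of sequenced reads was not used here. Counts were divided by these totals to give CPM. For each pair of libraries the ratio of CPM was given with its exact 95% interval (Clopper-Pearson, on the share of the summed count). A sequence was counted as higher or lower where it had at least 10 counts in at least 1 of the 2 libraries, a ratio of at least 2 either way and an interval that excluded 1. Shares of a library's tags carry exact Clopper-Pearson binomial 95% intervals, and a ratio of 2 count ratios carries an exact conditional interval. Without molecular identifiers, PCR copies are not independent molecules, so all intervals cover counting error only. With 1 library per group no test between conditions was possible, no p-value is given, and every comparison is between libraries. No fold is given for a single sequence against a library where it was not listed. The steps were tested on simulated Poisson counts with 200 changed sequences, a model that holds counting error alone: for tGCI26h against Sham, where changes were placed among 1031 sequences expected to reach the count minimum in both libraries, 95.0% of those changed 4-fold and 50.0% of those changed 2-fold were called, and 2.09% of 1052 unchanged ones were called. For HPC0h against tGCI26h, with 1258 such sequences, the values were 96.0%, 55.0% and 1.39% of 1805.

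Many sequences overlap. Sequences that share any stretch of 20 bases were joined into 307 families. A family was named after an RNA when a member held 1 of 98 short anchor sequences. These were of rRNA, tRNA, snRNA, Y RNA, 7SL, 7SK, BC1/ID-like RNA or let-7b. The anchors were written from general knowledge, partly after the deposited sequences had been looked at, and were not checked against a reference, because no genome or transcript sequence was used here. The RNA names are therefore provisional, and since these RNAs are conserved, a family can also hold fragments of the same RNA from another organism. The 222 families without an anchor are called unassigned and their sequences are not printed. Whether they come from the rat was not checked here either, so an unassigned sequence may be from another organism. No coordinates are given. Matches inside coding or long noncoding transcripts, planned as a list, were not run for the same reason. Planned lists (first base T, A at position 10, length up to 28 nt, not listed in IgG, and RNA classes) and an added list of rno_piR names were described by the median log2 ratio, with a pseudocount of 0.5 counts, and by its percentile among 10000 random lists of the same size matched on mean abundance. Random lists draw single sequences as if independent, whereas the lists hold overlapping fragments of fewer families, so a percentile overstates how far a list stands apart.

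The sequences named in the text followed a rule fixed in advance. For each comparison it takes the 10 higher and 10 lower sequences whose interval bound nearest to a ratio of 1 lay farthest from it (for IgG, the 10 higher), then the 10 most abundant sequences of each library and the 5 sequences per direction that changed oppositely in tGCI26h against Sham and HPC0h against tGCI26h, ranked by the smaller of their 2 changes. Of these, a selection is printed. RNA families are described after their values were seen. Other settings fixed before the data were examined were TMM factors, median-of-ratios size factors, the authors' normalized table, other count minimums and folds, totals without the 10 most abundant sequences, summing sequences that contain one another, and keeping sequences at least 2-fold above IgG. Family sums, other family lengths, totals without the 28S 5' end family, a thinned HPC0h library, U2 sums without the end variants of the leading U2 fragment (sequences that end as it does and lack only its first bases), and list shares without let-7b, the 28S 5' end family or tRNA-Glu were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, and TMM factors came from edgeR 4.0.16 in R 4.3.3.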

Results

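Small RNA recovered by Piwil2 RIP from rat hippocampal CA1 was profiled in 3 libraries (Sham, tGCI26h and HPC0h) beside an IgG control library, with 1 library per group. The listed sequences held 159215 tags in Sham, 222511 in tGCI26h, 830634 in HPC0h and 668857 in IgG. There were no replicates, so each difference is between libraries and its 95% interval covers counting error only.

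Fragments of ribosomal and transfer RNA made up most tags in all 4 libraries. Fragments of 28S rRNA, the RNA of the large ribosomal subunit, held 50.9% of tags in Sham (95% interval 50.6 to 51.1), 52.7% in tGCI26h (52.5 to 53.0), 71.6% in HPC0h (71.5 to 71.7) and 59.5% in IgG (59.4 to 59.6). Fragments of 18S rRNA, from the small subunit, held 15.9%, 21.4%, 15.5% and 20.2%. The tRNA-Glu fragments held 13.5% in Sham, 14.2% in tGCI26h, 6.44% in HPC0h and 9.99% in IgG. Unassigned sequences held 2.24%, 3.61%, 2.33% and 1.87% of tags in the same order. Sequences of 33 nt or longer held between 94.2% and 98.2% of tags. Sequences that began with T, the first base typical of primary piRNAs, held 29.2% of tags in Sham, 27.2% in tGCI26h, 15.9% in HPC0h and 23.9% in IgG, and without the tRNA-Glu fragments 16.3%, 13.6%, 9.76% and 14.3%.

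**Figure D1:**
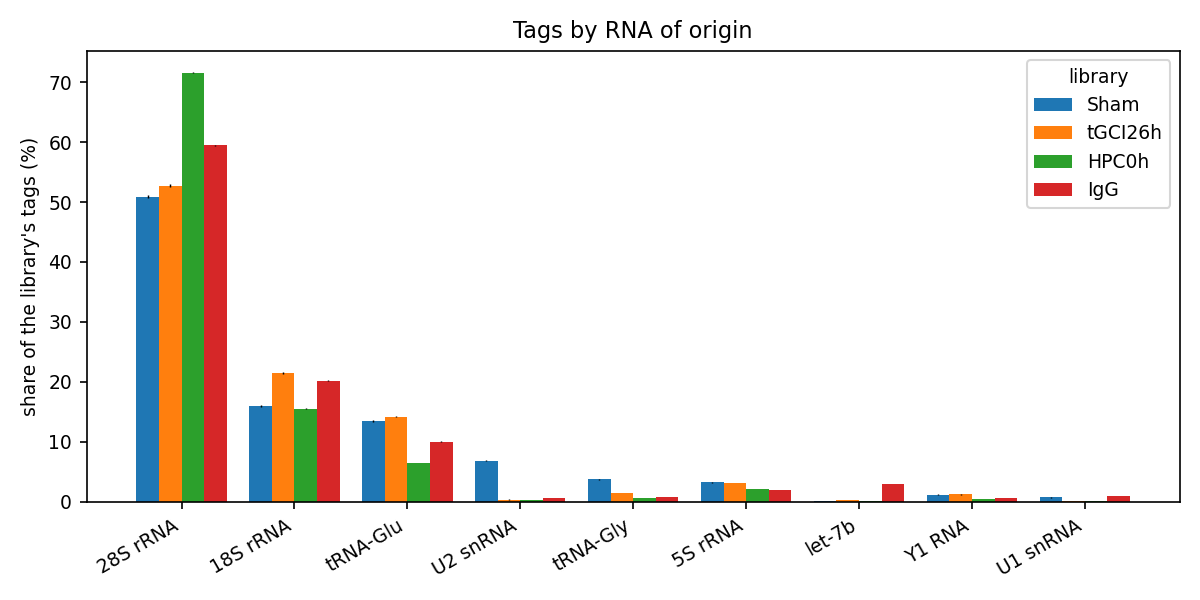
Share of each library's tags (vertical axis, percent) by RNA of origin (horizontal axis), 1 bar per library, with error bars for exact binomial 95% intervals. The 28S share was 71.6% in HPC0h against 50.9% in Sham, and the U2 share was 6.86% in Sham against at most 0.642% in the other libraries.

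The most abundant sequence in every library was novel_88_x12235, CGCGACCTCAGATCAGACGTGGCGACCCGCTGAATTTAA, from the 5' end of 28S rRNA. It held 13.1% of tags in Sham, 12.9% in tGCI26h, 19.8% in HPC0h and 16.04% in IgG. The tRNA-Glu fragment novel_2845_x640, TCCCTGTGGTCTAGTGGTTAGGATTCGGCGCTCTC, held 7.91%, 8.67%, 3.66% and 6.03%. The 5S rRNA fragment novel_11003_x177, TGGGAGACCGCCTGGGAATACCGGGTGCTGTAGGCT, held 2.02% in Sham, 1.98% in tGCI26h and 1.22% in HPC0h. The 10 most abundant sequences of each library held 47.2% of tags in Sham, 43.5% in tGCI26h, 48.5% in HPC0h and 47.3% in IgG, and 7 sequences were among the 10 in all 4 libraries.

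The IgG library is the control measured the same way. Ratios over it compare shares of listed tags. Higher or lower over IgG is therefore a difference in composition and does not measure the amount of RNA recovered. Over IgG, 239 of 1919 measured sequences were higher and 548 lower in Sham, 325 of 1961 were higher and 383 lower in tGCI26h, and 384 of 2159 were higher and 369 lower in HPC0h. Summing overlapping sequences by family, chosen after the data were seen, turned these splits to 48 higher and 35 lower, 66 and 30, and 28 and 41. Fragments of tRNA-Asp, overlapping sequences in 2 families, were higher over IgG in each Piwil2 library. Of the measured sequences 7 of 10 were higher in Sham, 15 of 16 in tGCI26h and 13 of 15 in HPC0h, and none was lower. As they overlap, these sequences are not independent. One of them, novel_3644_x506 with the sequence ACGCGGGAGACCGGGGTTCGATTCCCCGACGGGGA, was 21.7-fold higher in Sham (95% interval 13.2 to 37.5). Measured tRNA sequences as a class had a median log2 ratio over IgG of 1.26 in Sham and 1.38 in tGCI26h, each above all 10000 matched random lists, but -0.36 in HPC0h, at percentile 8.78. The 68 tRNA sequences fall into 12 families of overlapping fragments, whereas random lists draw single sequences, so such percentiles overstate how far a list stands apart. The miRNA let-7b, novel_4906_x381, TGAGGTAGTAGGTTGTGTGGT, went the other way. It is the only sequence given that name, and its length of 21 nt is the shortest listed, so its ratios describe this sequence alone. It held 2.96% of IgG tags and was 24.1-fold lower in Sham (95% interval 21.0 to 27.9), 11.9-fold lower in tGCI26h (11.0 to 13.0) and 59.3-fold lower in HPC0h (53.8 to 65.5).

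Among the 1891 sequences measured against IgG in all 3 comparisons, 30 were higher than IgG in all 3 and 95 were lower in all 3, in 16 and 34 families. The higher ones were 8 fragments of 18S rRNA, 8 of 28S rRNA, 7 of tRNA-Asp, 1 of 7SK and 6 unassigned sequences. Unchanged libraries, IgG included, drawn from the pooled shares of all libraries gave at most 1 in either direction over 100 simulated draws. These draws hold counting error only and do not show what the composition of the actual IgG library would give. Independent lists would share 3.40 and 21.7. These 3 comparisons share the IgG library, so part of the excess may come from that library.

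The leading sequences over IgG differed by library. In Sham the first 4 were end variants of a U2 snRNA fragment, led by novel_4560_x409 at 42.4-fold (35.6 to 50.8). The U2 tags together were 10.7-fold above IgG in Sham (10.3 to 11.1), and 2.09-fold (1.97 to 2.22) without the 5 end variants of that fragment. They were below IgG in tGCI26h, at a ratio of 0.553 (0.512 to 0.596), and in HPC0h, at 0.475 (0.452 to 0.499). Tags of U1 snRNA were below IgG in each Piwil2 library, at ratios of 0.763 (0.716 to 0.813) in Sham, 0.109 (0.0952 to 0.125) in tGCI26h and 0.0494 (0.0444 to 0.0547) in HPC0h. In tGCI26h the first was the unassigned novel_18422_x113, with 520 tags against 8 in IgG, a ratio of 195 (98.4 to 455). In HPC0h the first was the unassigned novel_20725_x103, with 82 tags and not listed in IgG, where the authors' normalized table gives 93 against 2, and the most abundant of the leading 10 was the unassigned novel_12673_x157, which held 4254 tags and was 9.70-fold above IgG (8.70 to 10.8). The family of novel_12673_x157, of 19 overlapping sequences, had 282.6 CPM in Sham, 1869.6 in tGCI26h, 8302 in HPC0h and 919 in IgG, and neither its RNA nor its organism of origin was identified here.

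The tGCI26h library was set against Sham to see which RNAs differed between these Piwil2 libraries, whether or not they lay above IgG. U2 snRNA, a component of the spliceosome, was the RNA that differed most among those with over 1% of tags in either library. It held 6.86% of Sham tags (95% interval 6.74 to 6.99) and 0.355% of tGCI26h tags (0.331 to 0.381), 19.3-fold lower in tGCI26h (17.98 to 20.8). Of 29 measured U2 sequences 20 were lower and none higher. The leading fragment novel_5060_x368, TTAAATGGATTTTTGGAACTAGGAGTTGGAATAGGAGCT, had 5131 tags in Sham and 10 in tGCI26h, a 717-fold lower ratio (389.6 to 1496). This fragment and its end variants, 5 sequences grouped after their values were seen, held 85.1% of U2 tags in Sham and 4.18% in tGCI26h, and the other U2 tags were 3.00-fold lower (2.75 to 3.27). U1 snRNA, also of the spliceosome, was 6.99-fold lower (6.06 to 8.09), with 8 of 11 measured sequences lower and 1 higher, and its fragment novel_426_x3250, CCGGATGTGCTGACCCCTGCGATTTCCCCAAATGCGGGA, 34.8-fold lower (23.0 to 55.4). All 4 measured tRNA-His sequences, from 1 family of overlapping fragments, were lower, and tRNA-His tags together were 6.98-fold lower (5.96 to 8.20).

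Other RNAs went both ways in tGCI26h against Sham. The tRNA-Gly fragments were 2.55-fold lower as a sum (2.44 to 2.66), with 1 of 3 measured sequences lower and 1 higher. The sum was set by rno_piR_005567, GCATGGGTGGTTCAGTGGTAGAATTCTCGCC, with 3.70% of Sham tags and 1.44% of tGCI26h tags. The tRNA-Gly fragments held 87.6% of the tags of all rno_piR names in Sham and 67.8% in tGCI26h. Of 15 measured tRNA-Asp sequences 9 were higher and none lower. Fragments of 18S rRNA were 1.34-fold higher as a sum (1.32 to 1.36), and 182 of 452 measured sequences were higher against 38 lower. The leading higher sequences were mostly rRNA fragments not listed in Sham, such as novel_13901_x144 of 18S rRNA with 205 tags in tGCI26h and novel_7068_x268 of 28S rRNA with 176 tags. The authors' normalized table gives them 792 against 3 and 746 against 19 in Sham. The 28S sum was 1.04-fold higher (1.03 to 1.05) and turned to 0.899 with TMM factors. Over 1366 measured sequences 372 were higher and 190 lower, in 84 and 64 families, and this split was 302 and 227 with TMM factors and 300 and 227 with median-of-ratios size factors.

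**Figure D2:**
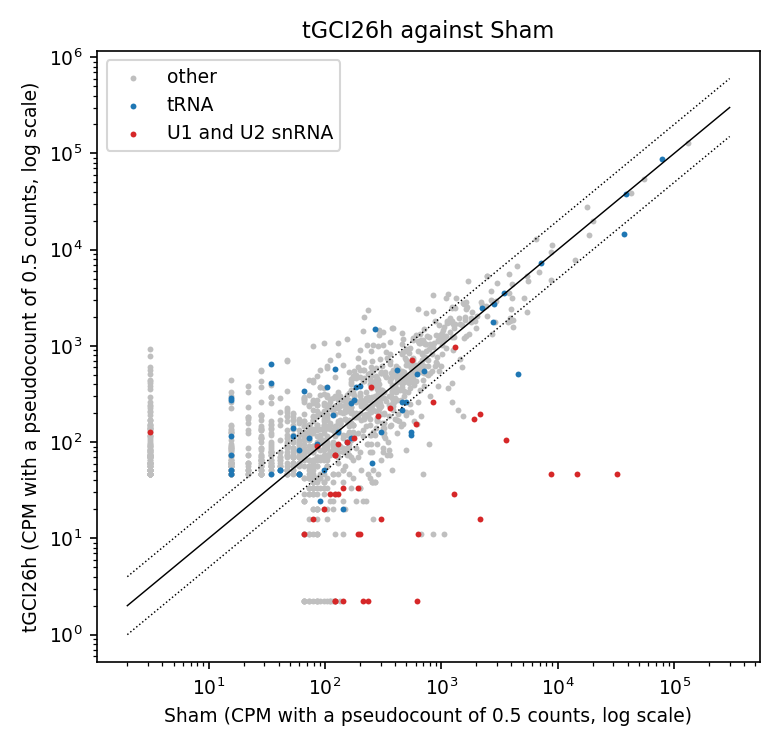
CPM in tGCI26h (vertical axis) against Sham (horizontal axis) on log scales with a pseudocount of 0.5 counts, 1 point per sequence with at least 10 counts in either library. The solid line marks equal CPM and the dotted lines a ratio of 2 either way, and the U2 fragment with 5131 tags in Sham and 10 in tGCI26h is the point farthest below the solid line. Blue marks tRNA, red U1 and U2 snRNA and grey all others.

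The HPC0h library was also set against tGCI26h. The names of the 2 libraries give different times (0 h and 26 h) but not the event from which each is counted. Whether the libraries also differ in time since ischemia is therefore not known. If they do, this comparison cannot separate time from treatment. Fragments of tRNA were lower in HPC0h, with 41 of 55 measured sequences lower and none higher, and a median log2 ratio of -1.96, below all 10000 matched random lists. The tRNA-Glu sum was 2.21-fold lower (2.18 to 2.24), the tRNA-Gly sum 2.16-fold lower (2.07 to 2.25), and 15 of 17 tRNA-Asp and all 5 tRNA-Lys sequences were lower. All 12 measured sequences of Y1 RNA, a small noncoding RNA bound by the Ro60 protein, were lower. They belong to 1 family of overlapping fragments, and their sum was 2.50-fold lower (2.38 to 2.62). Of 24 measured rno_piR sequences 19 were lower and 1 higher. These include 12 of the tRNA fragments, all lower, and 10 unassigned sequences, 5 of them lower and 1 higher.

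Fragments of 18S rRNA were 1.38-fold lower as a sum (1.37 to 1.40), which turned to a log2 ratio of 0.074 with totals without the 28S 5' end family. The 28S sum was 1.36-fold higher in HPC0h than in tGCI26h (1.35 to 1.37), and the family at its 5' end was 1.68-fold higher (1.67 to 1.69), with 91 of 197 measured sequences higher and none lower. The leading higher sequence was novel_800_x1940 of 28S rRNA, with 239 tags and not listed in tGCI26h, for which the authors' normalized table gives 283 against 12. The leading lower sequences were mostly unassigned: novel_18422_x113 had 4 tags against 520, a 485-fold lower ratio (188 to 1788), and novel_7583_x251 was 44.0-fold lower (34.2 to 57.5). The U2 sum was 1.16-fold lower (1.07 to 1.26) by library totals and 1.02-fold higher with TMM factors. Its parts moved apart by library totals: the 5 end variants were 6.03-fold higher (4.26 to 8.83) and the other U2 tags 1.58-fold lower (1.45 to 1.72). Over 2036 measured sequences 428 were higher and 428 lower. TMM factors turned this split to 537 higher and 347 lower, and totals without the 28S 5' end family to 695 and 267, whereas summing by family gave 21 and 76. The last 2 settings were chosen after the data were seen.

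**Figure D3:**
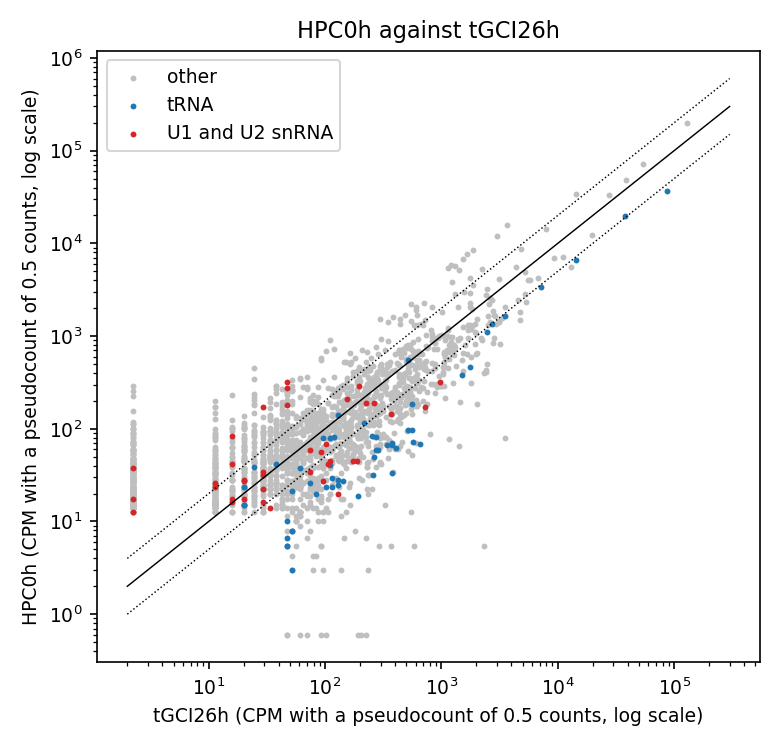
CPM in HPC0h (vertical axis) against tGCI26h (horizontal axis) on log scales with a pseudocount of 0.5 counts, 1 point per sequence with at least 10 counts in either library, with lines for equal CPM and a ratio of 2 either way. Of the 55 tRNA sequences (blue), 41 were counted as lower and none as higher, with U1 and U2 snRNA in red and all others in grey.

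Against Sham, HPC0h also had fewer tags of U2 and U1 snRNA. U2 was 22.5-fold lower (21.5 to 23.5), with 28 of 34 measured sequences lower, or 4.73-fold lower (4.42 to 5.06) without the 5 end variants, and U1 was 15.4-fold lower (13.8 to 17.4). Fragments of tRNA were lower in 29 of 48 measured sequences and higher in 2, and tRNA-Gly was 5.50-fold lower (5.30 to 5.71). The unassigned novel_12673_x157 was 24.7-fold higher (17.6 to 35.9). The 28S sum was 1.41-fold higher (1.40 to 1.42). Over 2020 measured sequences 514 were higher and 322 lower, and summing sequences that contain one another turned this to 92 and 126.

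Taking tGCI26h against Sham and HPC0h against tGCI26h together, 183 sequences were higher in tGCI26h than in Sham and lower in HPC0h than in tGCI26h, and 76 went the opposite way, among 1347 measured in both comparisons. The first set held 81 fragments of 18S rRNA, 50 of 28S rRNA, 9 of tRNA-Asp, let-7b and 33 unassigned sequences, and the second held 48 of 28S rRNA, 13 of 18S rRNA, 6 of U2 snRNA and 6 unassigned sequences. An example of the first is novel_17472_x118 of 28S rRNA, not listed in Sham and with 125 and 43 tags in tGCI26h and HPC0h (15, 533 and 58 in the authors' normalized table), and of the second novel_6066_x308, grouped with 18S rRNA, with 105, 2 and 165 tags. Both comparisons share the tGCI26h library. Unchanged libraries, a model of counting error only, gave at most 6 and 7 such sequences over 100 simulated draws. Independent lists would share 117 and 24.9. In the same direction, 13 sequences were higher in both comparisons and 13 lower in both, where independent lists would share 53.6 and 54.5. Part of the excess of opposite changes, and of this shortfall, may come from the shared library, so the counts do not show a reversal between conditions. The split of opposite changes was 137 and 108 with TMM factors and 142 and 102 with median-of-ratios size factors. It was 101 and 20 with at least 50 counts, 124 and 16 among sequences at least 2-fold above IgG, and 28 and 3 in summed families.

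The lists defined by sequence features differed between comparisons. Sequences of 28 nt or shorter held 0.683% of tags in Sham, 1.18% in tGCI26h, 0.273% in HPC0h and 3.27% in IgG. Without let-7b they held 0.560%, 0.936%, 0.223% and 0.316%. In HPC0h against tGCI26h 32 of 47 were lower and none higher, with a median log2 ratio of -1.74, below all 10000 random lists. Sequences with A at position 10, a base typical of secondary piRNAs, held 35.8%, 35.3%, 47.6% and 46.8% of tags in the order Sham, tGCI26h, HPC0h and IgG, and without the 28S 5' end family 7.74%, 9.52%, 7.24% and 11.4%. Their median log2 ratio was 0.18 in tGCI26h against Sham, at percentile 0.04. Median-of-ratios size factors, which shift every log2 ratio by -0.22, gave -0.033 at the same percentile. With at least 50 counts the median was 0.15, at percentile 2.96. In HPC0h against tGCI26h the median was 0.22, at percentile 99.21. With a pseudocount of 5 counts it was -0.17, at percentile 99.965, while the median of all measured sequences moved from 0.12 to -0.32. Sequences that began with T had a median of 0.27 in tGCI26h against Sham, at percentile 36.37, although their sum was 1.07-fold lower (1.06 to 1.09). In HPC0h against tGCI26h their median was 0.07, at percentile 12.11, and -0.18, at percentile 0.73, with at least 50 counts. With a pseudocount of 5 counts it was -0.31, at percentile 47.21, near the -0.32 of all measured sequences. Their sum was 1.71-fold lower (1.69 to 1.73). The sequences named rno_piR had a median of -2.00 in HPC0h against tGCI26h, below all random lists, but 12 of the 24 measured were tRNA fragments. In tGCI26h against Sham their median was 0.63, at percentile 59.85, although their sum was 1.98-fold lower in tGCI26h (1.91 to 2.06). Sequences not listed in IgG held 0.162% of tags in Sham, 0.312% in tGCI26h and 0.311% in HPC0h. The list is not free of IgG signal, since in the authors' normalized table its sum was only 1.76-fold above IgG in Sham, 3.10-fold in tGCI26h and 2.72-fold in HPC0h. By raw tags their sum was 1.93-fold higher in tGCI26h than in Sham (1.67 to 2.23) and at a ratio of 0.996 (0.916 to 1.08) in HPC0h against tGCI26h. Their medians were 1.45 and 1.56 in these comparisons, at percentiles 91.27 and 96.44. Of the 483 sequences in this list, 435 were listed in HPC0h, 124 in tGCI26h and 57 in Sham. A positive median in HPC0h against tGCI26h can therefore follow from how the list is defined and from the depth of HPC0h. With a pseudocount of 5 counts the medians were 0.68 and -0.18, at percentiles 86.885 and 68.125.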

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

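The counts in this part were chosen after the data had been seen.

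The normalized table lists sequences that the raw table does not, and no comparison used them. Counting those with a normalized value of at least 10 that was also at least 2-fold above the IgG value gave 18 sequences in Sham, 12 in tGCI26h and 0 in HPC0h. In the opposite direction, 12 sequences had an IgG value of at least 10 and at least 2-fold above Sham, 12 above tGCI26h and 14 above HPC0h. The highest value in a Piwil2 library was 33 for novel_13701_x146 in tGCI26h, against 2 in IgG. All sequences listed only in the normalized table together held 0.103% of the normalized total in Sham, 0.133% in tGCI26h and 0.132% in HPC0h.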

How the results depend on the processing

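Family sums, totals without the 28S 5' end family, the thinned HPC0h library and U2 sums without end variants were tried only after the results had been seen. The total number of higher and lower sequences stayed within 1.5 times of those reported under TMM factors, median-of-ratios size factors, the authors' normalized table, no count minimum, a 1.5-fold threshold and totals without the 10 most abundant sequences. Stricter thresholds and summed sequences lowered them, by construction. In the order Sham, tGCI26h and HPC0h over IgG, tGCI26h against Sham, HPC0h against tGCI26h, HPC0h against Sham and opposite changes, requiring at least 50 counts gave 426, 359, 408, 234, 503, 511 and 121 sequences, and a 4-fold threshold gave 473, 401, 308, 338, 430, 500 and 99. Summing sequences that contain one another gave 197, 231, 185, 178, 226, 218 and 80 items, and summing families gave 83, 96, 69, 70, 97, 85 and 31. Keeping sequences at least 2-fold above IgG left 289 for tGCI26h against Sham, 433 for HPC0h against tGCI26h, 382 for HPC0h against Sham and 140 opposite changes. Summing also changed which direction held more items: contained sequences gave 143 higher and 88 lower in tGCI26h over IgG, 78 and 107 in HPC0h over IgG, 67 and 159 in HPC0h against tGCI26h and 92 and 126 in HPC0h against Sham, and families gave 48 and 35 in Sham over IgG and 28 and 57 in HPC0h against Sham; the cause was not tested. A 1.5-fold threshold gave 490 higher and 566 lower in HPC0h over IgG, and no count minimum gave 412 and 383 in tGCI26h over IgG. Thinning HPC0h to the tGCI26h total gave 314 higher and 396 lower against tGCI26h.

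TMM factors shifted every log2 ratio by -0.21 in tGCI26h against Sham and by 0.24 in HPC0h against tGCI26h. Totals without the 28S 5' end family turned the log2 ratio of 18S rRNA in HPC0h against tGCI26h to 0.074, which follows from the larger share of that family in HPC0h. The 10 most abundant sequences held 43.9% in Sham, 40.6% in tGCI26h, 46.5% in HPC0h and 45.1% in IgG of the authors' normalized totals; the cause of the lower shares was not tested. Of 75 list medians 40 lay outside the central 95% of random lists, 43 and 40 of 75 did with a pseudocount of 5 counts and median-of-ratios factors, and 35 of 59 with at least 50 counts. Without the end variants of the leading fragment the log2 ratio of U2 was -1.58 in tGCI26h against Sham and 1.06 in Sham over IgG. The median of unassigned sequences in HPC0h over IgG was -0.025 with at least 50 counts, above instead of below that of all measured sequences, and their summed ratio was 1.24; the cause was not tested. Of 360 values of named sequences under other scalings 346 stayed within their interval, 14 left it and none changed sign. Those sequences were picked in the same data for ratios far from 1, so shifts as small as those above could hardly change a sign. Of the values of RNA classes under other settings, 34 moved, 1 reversed and 10 stayed the same. This count does not measure how stable the direction of every RNA sum is. With TMM factors the 28S ratio in tGCI26h against Sham went from 1.04 to 0.899, and the tRNA-Glu ratio from 1.05 to 0.912. The U2 ratio in HPC0h against tGCI26h went from 0.860 to 1.02. Other sums, such as U1 and U2 in tGCI26h against Sham, kept their direction. No paired analysis was possible because each group had 1 library, and no library could be left out. The smaller Sham and tGCI26h totals limit what can be seen of rare sequences there.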

Other observations

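All tests in this part were chosen after the result they concern had been seen. Further RNAs differed in share. BC1/ID-like RNA is like the neuronal noncoding RNA BC1 or like ID repeats, which were not told apart here. All 4 of its measured sequences, from 1 family of overlapping fragments, were higher in tGCI26h than in Sham and in tGCI26h than in IgG. This RNA held 0.0264% of tags in Sham, 0.0795% in tGCI26h, 0.0438% in HPC0h and 0.0233% in IgG. Mitochondrial 16S rRNA held 0.149%, 0.268%, 0.0893% and 0.259% in the same order. Unassigned tags began with T in 24.9% of cases in Sham, 20.2% in tGCI26h, 17.98% in HPC0h and 31.3% in IgG.

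Most of the abundant IgG sequences had a similar share in the Piwil2 libraries. Of the 10 most abundant IgG sequences 9 were within 2-fold of their IgG share in each Piwil2 library, the exception being let-7b. Of each Piwil2 library's own 10 most abundant, 8 were within 2-fold of IgG in Sham and 9 each in tGCI26h and HPC0h, and those outside included in Sham the U2 fragment novel_5060_x368, 38.7-fold above IgG (35.5 to 42.3), and the tRNA-Gly fragment rno_piR_005567, 5.15-fold above (4.95 to 5.35). Whether the sequences at a similar share were background RNA or were bound by Piwil2 was not tested.

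U2 snRNA fragments had a higher share in Sham than in the other 3 libraries. Carry-over of nuclear RNA that raises all snRNA fragments alike would leave the U2 to U1 count ratio equal. In Sham this ratio was 14.0 times that in IgG (95% interval 13.02 to 15.1), and 2.74 times (2.51 to 2.99) without the 5 end variants of the leading fragment. The ratio was 0.684 in IgG, but also higher in tGCI26h (3.46) and HPC0h (6.59), so the contrast with IgG is not particular to Sham. Without the end variants it was 0.520 in IgG, 1.43 in Sham, 3.32 in tGCI26h and 4.66 in HPC0h. Against tGCI26h the Sham ratio was 2.77 times as high (2.35 to 3.25) but 0.429 times (0.362 to 0.508) without them. Against HPC0h it was 1.45 times (1.28 to 1.65) but 0.306 times (0.267 to 0.350). These ratios therefore do not tell carry-over apart from other explanations. Totals set by a few abundant sequences would move every ratio alike. The other 1337 measured sequences had a median Sham to tGCI26h ratio of 0.765, with the central 95% between 0.0274 and 8.15. The U2 sum was at 19.3, and at 3.00, inside that range, without the end variants. Dividing by library totals keeps the other sequences near a ratio of 1 as a sum, so this contrast cannot decide the question. The U2 ratio of tGCI26h to Sham was 0.0517 by library totals, 0.0449 with TMM factors and 0.0445 with median-of-ratios size factors. The sham condition itself may be the source, but with 1 Sham library it cannot be told apart from a property of that library.

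An excess of lower over higher sequences in HPC0h against tGCI26h had been looked for, and the counts were equal at 428 each. Summed by family, 21 families were higher and 76 lower, a quotient of 3.62. Totals that left out the 28S 5' end family gave 37 higher and 52 lower, a quotient of 1.41, but this setting shifts every log2 ratio by 0.54, which lowers the quotient whatever the cause, so whether the larger share of that family in HPC0h lies behind the skew stays open. With HPC0h thinned to the tGCI26h total, 16 families were higher and 73 lower, a quotient of 4.56, so the skew was also present at equal depth. A deeper HPC0h library that lists more rare sequences would add higher families. Thinning could therefore hardly have lowered the quotient, and it does not decide what role depth has. The tRNA-Glu sum remained lower in HPC0h without the 28S 5' end family, at a ratio of 0.660 (95% interval 0.650 to 0.669), and a difference between the conditions stays open and untested.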
